A study of Mus musculus with 13 samples.

How the data were processed

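RNA sequencing of mouse mammary gland was available for 13 libraries. Per the labels' protocols, total RNA came from flash-frozen glands, was purified on silica columns (RNeasy Mini), converted to libraries with the TruSeq RNA kit and sequenced on an Illumina HiSeq instrument. The labels distinguish females with a conditional knockout of Jak1 from wildtype controls, at day 7 of lactation (3 control and 3 knockout libraries) and at day 2 of involution (3 control and 4 knockout libraries). Groups, stages and the number of each mouse were taken from the library titles. The labels' protocol speaks of 7 knockout females and 6 control mice, whereas the titles carry 11 different numbers, because M43768 (control) and M43767 (knockout) stand at both stages. The libraries within a stage therefore come from separate mice, and whether any mouse was sampled at both stages was left open.

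Each stage has its own deposited table of FPKM (mapped fragments relative to transcript length and library size) with 23951 gene symbols in the same order, none duplicated. Per the submitters' processing notes the authors used CASAVA, cutadapt and TopHat with the mouse genome build mm9. Versions, the program that turned alignments into FPKM, its gene annotation and its scaling are not given in the sources used here. The genome supplied for this work is another build, so no coordinates are printed. The deposited FPKM tables may have been normalized separately, so tests were made within a table, and levels of the stages are only set side by side.

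Exact zeros in the deposited FPKM tables entered the fits as values of 0, although some of them stand for entries without an estimate rather than for absent transcripts, and which ones do is not given. The caseins Csn1s1, Csn1s2b and Csn2 and the whey acidic protein gene Wap, which a lactating gland transcribes abundantly, were listed at 0 in all 13 libraries. For genes listed at 0 in every library of 1 group the range over the libraries of the other group is given and no fold change. Their fitted contrasts between stages are printed as results of the joint fit, depend on the pseudocount and are no bounds. Of all symbols, 4649 were listed at 0 in all 13 libraries.

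The number of sequenced fragments is not given in the sources used here. Low values nevertheless rise in steps of 1 fragment, whose worth in FPKM depends on the gene's length and on the library. The relative depth of the libraries of a table was therefore estimated from the ratio at which the low values of each pair of libraries pile up (values above 0 and under 0.3 FPKM). After this correction 70.9% of 27125 pairs of low values at lactation, and 69.5% of 33942 at involution, lay on ratios of whole numbers up to 5 within 0.02 on the log2 scale. With the ratios shifted off the whole numbers, the shares were 3.86% and 3.76%. The estimate, tested on simulated data of 20000 genes in 6 libraries, returned the simulated depths. It gives depth relative to the mean of a table and no count per gene, so no counting intervals are given.

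Within each table, FPKM were divided by a median-of-ratios factor per library, computed over genes with at least 1 FPKM in every library, and transformed to log2(rescaled FPKM + 1). The factors ran from 0.954 to 1.12 at lactation and from 0.980 to 1.02 at involution. Because of the pseudocount of 1, log2 fold changes understate the change of low genes. Genes with at least 1 FPKM in at least 3 libraries of a fit were tested with limma 3.58.1 (lmFit, and eBayes with an intensity trend) in R 4.3.3, without covariates, because the labels give no batch. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The difference of the knockout effect between stages was tested in a joint fit of the 13 libraries, each table rescaled within itself, as the effect at involution minus the effect at lactation. Errors beside log2 fold changes are standard errors, and errors beside FPKM are standard deviations over the libraries of a group. FPKM are printed as deposited.

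A total of 29 gene lists, 16 of pathways and 13 of cell types, were fixed before the data were examined. The pathway lists were the JAK-STAT family, cytokines and receptors that use JAK1, STAT3 targets and acute phase, interferon-stimulated genes, MHC class I presentation, MHC class II presentation, milk proteins, STAT5 targets and lactation regulators, milk lipid synthesis, lysosome and cathepsins, cell death, matrix proteolysis, NF-kB targets and inflammatory mediators, the TGF-beta pathway, cell cycle, and immediate early and stress genes. The cell type lists were luminal epithelium, basal epithelium, adipocytes, fibroblasts, endothelium, macrophages, neutrophils, T and NK cells, B and plasma cells, lymph node stroma, skeletal muscle, skin keratinocytes and erythrocytes. Lists with at least 5 members tested were compared with the other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and limma's fry, which asks whether the members move one way on balance, were run beside it. Members were also counted past the threshold when adjusted over the list alone. For each list, the mean log2 value per library was compared between groups by a two-sided exact permutation test, in which 3 against 3 libraries cannot go below p = 0.1 and 3 against 4 cannot go below p = 0.0286. Adjusted over the lists, this test therefore cannot pass the threshold at lactation. At involution it can pass only if many lists reach the smallest p.

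The genes named in the text followed a rule set before the data were examined. It takes the JAK-STAT family, and up to 10 genes per direction and stage past the threshold without overlap between groups. Where fewer than 5 passed, genes with the smallest p filled the number up to 5, given as values. Up to 4 members of each list with the smallest p, up to 5 genes per direction for the difference between stages, and 8 genes for levels side by side complete it. Predicted gene models, microRNA entries and immunoglobulin or T cell receptor segments were left out of these choices. Of those past the threshold, 2 microRNA entries at involution and 3 in the difference between stages were left out in this way. Single values of 2 genes that the rule names are not reported here. Genes outside the rule are said to be chosen after their values were seen.

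Alternatives set before the data were examined were FPKM as deposited, quantile normalization, scaling to the total outside the milk proteins, a pseudocount of 0.1, no filter, robust empirical Bayes, array weights, the number in the titles as a block in the joint fit, an estimated correlation in the list tests of each stage, and leaving out each library in turn. Fits without genes listed at 0 in every library of 1 group, and also without microRNA and other short RNA entries, were added after the data were examined, as were the alternatives other than the block for the lists of the difference between stages.

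The fits were tested on simulated data with known changes. These were placed only in genes whose mean FPKM lay well above the expression filter, so the shares do not cover genes near it. At lactation (9700 simulated genes) 17.9%, 59.1% and 81.8% of genes changed by 1, 2 and 3 on the log2 scale passed the threshold. At involution (12710 genes) the shares were 32.8%, 88.1% and 93.9%, and for the difference between stages (12890 genes) 5.97%, 67.2% and 87.9%. Among the genes that passed, 11 of 116, 9 of 152 and 15 of 122 had not been changed. A list whose members were all moved by -1 on the log2 scale passed at both stages, and none of 20 and 22 unmoved lists did. The genes were simulated independently of each other, so this does not show how often unmoved lists pass when their genes vary together. In the data, splits of the involution libraries often passed as many lists as the labels did (15 of 35, the labelled split included). Plots were drawn with matplotlib 3.10.9.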

Results

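Gene expression was measured by RNA sequencing in whole mammary glands of mice that lack the tyrosine kinase JAK1 conditionally and of wildtype controls. JAK1 transmits signals of cytokines of the interleukin 6 and interferon classes, in part through the transcription factor STAT3. The study addressed what JAK1 contributes to inflammatory cytokine signals and to the remodelling of the gland after suckling ends. At day 7 of lactation there were 3 control libraries (M42186, M43768 and M44175, each M with the mouse's number) and 3 knockout libraries (M44174, M42734 and M43767). At day 2 of involution there were 3 control libraries (M44448, M43768 and M43914) and 4 knockout libraries (M43196, M43767, M44176 and M44440). Relative to the mean of its table, depth ran from 0.7395 (control M44175) to 1.315 (knockout M44174) at lactation, and from 0.513 (knockout M43196) to 1.59 (knockout M44440) at involution. Between libraries of a stage, log2 values correlated with Pearson coefficients across genes of 0.892 to 0.970 at lactation and 0.895 to 0.935 at involution. Control M44175 stood apart on the first principal component at lactation, which held 49.4% of the variance, and its FPKM summed to 871630 against 312976 to 421592 in the other 5 libraries. One short RNA entry, Mir6236, took from 3.05% (control M43768 at involution) to 44.0% (knockout M43196) of a library's total FPKM.

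Jak1 itself was at similar levels in libraries labelled control and knockout. At lactation Jak1 stood at 14.2, 14.0 and 6.18 FPKM in the controls and at 9.51, 10.2 and 11.2 FPKM in the knockouts (log2 difference -0.00 ± 0.35, adjusted p = 0.999 with limma). Its sign turned without control M42186 (0.22) or M43768 (0.19), without knockout M44174 (0.05) or M42734 (0.01), and with scaling to the total outside the milk proteins (0.25) or a pseudocount of 0.1 (0.01), whereas it was -0.41 without control M44175. At involution the values were 24.3, 24.0 and 24.6 FPKM in the controls and 22.999, 22.2, 26.3 and 17.3 FPKM in the knockouts (log2 difference -0.12 ± 0.17, adjusted p = 0.989). An FPKM over the whole gene in whole tissue counts transcripts of cells outside the deletion and transcripts that lack only the deleted part, so it does not check the labels. Groups are named below as labelled. Of the other family members, Stat3 stood at 97.0 ± 13.9 FPKM in the controls and 62.8 ± 4.54 FPKM in the knockouts at involution (n = 3 and 4, log2 difference -0.59 ± 0.17, adjusted p = 0.480 with limma), with every knockout below every control. Jak2, Jak3, Tyk2, Stat2, Stat5a, Stat5b and Stat6 differed by -0.33 (Stat5a) to 0.10 (Tyk2) on the log2 scale at involution, with adjusted p from 0.947 to 0.998. The signs of Stat6 (-0.03) and Tyk2 (0.10) turned without 1 library, Stat6 without M44448 (0.11) or M44176 (0.02) and Tyk2 without M44440 (-0.03). At lactation these 7 members and Stat3 differed by -0.07 (Stat5a) to 0.27 (Tyk2), each with an adjusted p of 0.998, and the signs of all but Stat5b turned under some scaling, under array weights or without 1 library. Stat4 was below the expression filter at both stages. As a list, the 10 tested family members had a median log2 difference of 0.05 at lactation (camera adjusted p = 0.718) and of -0.13 at involution (adjusted p = 0.0751).

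At day 2 of involution, knockout glands held far less transcript of the secreted proteins osteopontin and orosomucoid 2, and far more of agouti. Spp1, which encodes the secreted phosphoprotein osteopontin, fell from 8896 ± 3493 FPKM in the controls to 263 ± 219.6 FPKM in the knockouts (n = 3 and 4, log2 fold change -5.29 ± 0.61, adjusted p = 0.0363). Orm2, an orosomucoid of the acute phase, fell from 469.9 ± 252 to 46.9 ± 10.3 FPKM (log2 fold change -3.17 ± 0.34, adjusted p = 0.0245), and part of its reads may be split with the similar gene Orm1. Nfasc, a cell adhesion molecule, fell from 2.19 ± 0.293 to 0.236 ± 0.155 FPKM (log2 fold change -1.36 ± 0.17, adjusted p = 0.049999). In the other direction the agouti gene a, which encodes a secreted signalling protein of coat colour, rose from 0.815 ± 0.269 to 287 ± 112 FPKM (log2 fold change 7.26 ± 0.29, adjusted p = 1.62e-05). Its level did not follow the labels at lactation, where control M42186 stood at 652 FPKM and the knockouts at 186 to 321 FPKM. At involution all 4 knockout libraries lay on 1 side of all 3 controls in each of these genes.

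Of 12509 genes tested at involution, 9 passed the threshold with limma, 2 higher and 7 lower in the knockouts, and 855 (6.84%) had an unadjusted p under 0.05. In 887 genes (7.09%) the groups did not overlap, where 2 in 35 regroupings would separate them by chance. The other 5 of the 9 genes were listed at 0 in all libraries of 1 group. Csn1s2a, a casein, was listed at 0 in the 4 knockouts and at 20351 to 41984 FPKM in the controls. Trf, which encodes transferrin, was listed at 0 in the 3 controls and at 2293 to 7718 FPKM in the knockouts. Cdk8, a kinase of the mediator complex, was listed at 0 in the knockouts and at 9.06 to 11.6 FPKM in the controls. The same held for the microRNA entries Mir7036b (547 to 922 FPKM in the controls) and Mir1905 (109 to 190 FPKM), which were chosen after their values were seen. Without genes listed at 0 in 1 whole group, only gene a remained past the threshold, and the adjusted p of Orm2, Spp1 and Nfasc became 0.0858, 0.0954 and 0.0954. With short RNA entries left out too, a, Orm2 and Spp1 passed. Leaving out control M44448, M43768 or M43914 left 2, 2 and 3 genes past the threshold. Nfasc and the 4 genes listed at 0 in all knockouts then missed the expression filter, and Spp1, and without M44448 or M43768 Orm2, lost the threshold. The number was 20 with scaling to the total outside the milk proteins, 14 with robust empirical Bayes and 20 with array weights.

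The calls of the 3 lower genes that were measured in both groups depended on single libraries and on the processing, although their sign did not turn in any setting. With no filter Orm2 and Spp1 lost the threshold (adjusted p = 0.0863 and 0.156), as Nfasc did with a pseudocount of 0.1 (0.120). Orm2, with adjusted p from 1.07e-04 to 0.182 over 16 alternatives, had 0.0553, 0.182, 0.0934, 0.0782 and 0.0703 without M44448, M43768, M43196, M43767 and M44440. Spp1 (3.22e-09 to 0.189 over 16 alternatives) had 0.189, 0.156, 0.166, 0.0757, 0.0849 and 0.0811 without M44448, M43768, M43914, M43767, M44176 and M44440. Nfasc (0.0226 to 0.138 over 13 alternatives) had 0.0568, 0.138, 0.104 and 0.0825 without knockouts M43196, M43767, M44176 and M44440, and did not reach the expression filter without any of the 3 controls. Gene a passed in all 16 alternative settings, with adjusted p up to 8.83e-04.

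Just short of the threshold, Saa3, a serum amyloid of the acute phase, stood at 445 ± 115 FPKM in the controls and 36.5 ± 18.8 FPKM in the knockouts (log2 difference -3.69 ± 0.46, adjusted p = 0.0514). It passed under quantile normalization, scaling to the total outside the milk proteins, robust empirical Bayes, array weights and without knockout M44440 (adjusted p from 1.52e-05 to 0.0345). Higher in the knockouts, but not past the threshold, were Ccnd1, which encodes the G1 cyclin D1 (3.37 ± 0.445 and 11.2 ± 3.08 FPKM, adjusted p = 0.0898), and Egln3, an oxygen-dependent prolyl hydroxylase (3.85 ± 0.0384 and 11.3 ± 2.57 FPKM, adjusted p = 0.0636). The calcium-binding protein gene S100a4 stood at 41.7 ± 5.60 and 117 ± 24.1 FPKM (adjusted p = 0.0722). Each of these genes separated the groups completely, and each passed with array weights, as S100a4 did with quantile normalization (adjusted p = 0.0328) and Egln3 with robust empirical Bayes (0.0434).

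The list of STAT3 targets and acute phase genes was lower in the knockouts at involution. Of 31 members tested, 23 had a negative log2 difference, the median was -0.62, and camera gave an adjusted p of 1.46e-10 (adjusted p = 0.108 with an estimated correlation, unadjusted fry p = 7.28e-04). Over all genes 1 member, Orm2, passed the threshold, whereas 15 members were lower and 4 higher when adjusted over the list alone. Socs3, a feedback inhibitor that STAT3 induces, stood at 23.4 ± 4.51 FPKM in the controls and 9.47 ± 1.37 FPKM in the knockouts (log2 difference -1.19 ± 0.17, adjusted p over all genes 0.0898). Lrg1, a leucine-rich glycoprotein of the acute phase, stood at 726 ± 102 and 288 ± 80.8 FPKM (log2 difference -1.35 ± 0.29, adjusted p = 0.276). The 4 members that were higher adjusted over the list alone, chosen after their values were seen, were Hp, Il1r1, Nupr1 and Itih4, and both Hp, a haptoglobin, and Itih4 encode plasma proteins of the acute phase. Hp stood at 240.1 ± 82.2 FPKM in the controls and 796 ± 387 FPKM in the knockouts. Of the other lower members, Lcn2 stood at 10085 ± 3172 and 3694 ± 1353 FPKM, Igfbp5 at 829 ± 149 and 367 ± 107 FPKM, and Cd14, chosen after its values were seen, at 1879.5 ± 427 and 758 ± 202 FPKM. Saa1, Saa2 and Saa3, and Orm1 and Orm2, are similar copies whose shares of the reads are uncertain. The mean log2 value of the list was lower by 0.78 ± 0.14 in the knockouts, with the groups apart, in an exact permutation test (p = 0.0286, the smallest that 35 regroupings allow, adjusted over the lists 0.386). With the preset correlation the list passed in every one of the 16 alternatives, those that leave out 1 library included (adjusted p up to 2.69e-07).

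**Figure D1:**
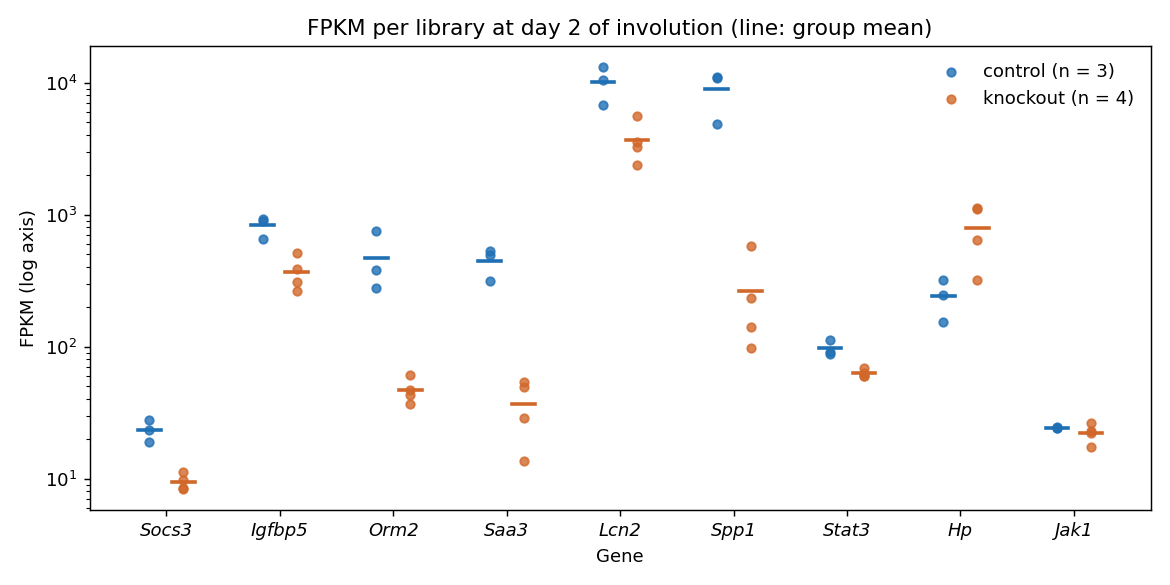
FPKM of 9 genes (log axis) in each of 3 control (blue) and 4 knockout (orange) libraries at day 2 of involution, with lines at the group means. Socs3, Igfbp5, Orm2, Saa3, Lcn2, Spp1 and Stat3 lie lower in every knockout library than in every control library, Hp lies higher, and Jak1 overlaps; of these genes, Orm2 and Spp1 passed the threshold over all genes.

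Cell cycle genes were higher as a list in the knockouts at involution, at low levels. All 27 tested members had a positive log2 difference, with a median of 0.53 and a camera adjusted p of 1.86e-13 (adjusted p = 0.461 with an estimated correlation). No member passed over all genes or when adjusted over the list alone. Mcm5, part of the replicative helicase, stood at 1.58 ± 0.253 FPKM in the controls and 2.99 ± 0.503 FPKM in the knockouts, and the mitotic genes Aurka and Cdc20 at 1.19 ± 0.278 and 2.21 ± 0.588 FPKM and at 1.16 ± 0.247 and 2.85 ± 1.48 FPKM. The mean log2 value of the list was higher by 0.51 ± 0.16, again with the groups apart (exact permutation p = 0.0286, adjusted 0.386). Milk proteins were lower as a list (12 tested, 9 negative, median -0.37, camera adjusted p = 7.59e-05, and adjusted p = 0.413 with an estimated correlation), a call that was lost without control M43768 or M43914 (median -0.13 and -0.45, adjusted p = 0.0969 and 0.218). Without the listed-at-0 gene Csn1s2a the median was -0.33. The mean log2 value of the list then differed by -0.30 ± 0.32, with the groups overlapping (exact permutation p = 0.429, adjusted 0.890). Besides Csn1s2a, its members with the smallest p were Lpo, lactoperoxidase (3.70 ± 0.909 and 1.63 ± 0.764 FPKM), and Cel, a lipase of milk (196 ± 91.7 and 99.98 ± 53.9 FPKM), and neither passed the threshold. NF-kB targets and inflammatory mediators were lower (17 tested, 14 negative, median -0.21, adjusted p = 0.0379, and adjusted p = 0.524 with an estimated correlation), among them Il1b at 3.69 ± 1.47 and 1.64 ± 0.697 FPKM. Matrix proteolysis genes were higher (16 tested, 14 positive, median 0.26, adjusted p = 0.0229, and adjusted p = 0.524 with an estimated correlation), among them Mmp3, stromelysin, at 26.6 ± 11.9 and 64.3 ± 26.8 FPKM. No member of the NF-kB or matrix lists passed the threshold, singly or adjusted over the list alone. The NF-kB call was lost without M43768, M43914, M43196, M43767 or M44176 (median -0.14, -0.17, -0.18, -0.25 and -0.26, adjusted p = 0.180, 0.132, 0.0881, 0.1004 and 0.0974) and with quantile normalization, scaling to the total outside the milk proteins or a pseudocount of 0.1 (adjusted p = 0.0575, 0.0513 and 0.0666), and the matrix call without M43768, M43196 or M44176 (median 0.11, 0.16 and 0.19, adjusted p = 0.189, 0.0673 and 0.0756) and with no filter (0.103).

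Beside these lists, markers of fibroblasts, macrophages, adipocytes and basal epithelium were higher in the knockout glands at involution with the preset correlation. Luminal epithelial markers showed no common direction. All 8 fibroblast markers had a positive log2 difference (median 0.77, camera adjusted p = 7.59e-05, and adjusted p = 0.563 with an estimated correlation). The collagen gene Col3a1 stood at 90.5 ± 33.2 FPKM in the controls and 205.7 ± 88.9 FPKM in the knockouts. The median of this list was 1.17 without control M44448 and 0.49 without control M43768. Of 12 macrophage markers 11 were positive (median 0.35, adjusted p = 0.00546, and adjusted p = 0.657 with an estimated correlation), led by the mannose receptor gene Mrc1 at 5.85 ± 0.983 and 11.1 ± 3.01 FPKM, and the call was lost without knockout M43196 (median 0.18, adjusted p = 0.161), while the median was 0.61 without knockout M44440. All 11 adipocyte markers were positive (median 0.69, adjusted p = 0.0229, and adjusted p = 0.780 with an estimated correlation), and the call was lost without M43768, M43914, M43767 or M44176 (median 0.81, 0.39, 0.54 and 0.41, adjusted p = 0.0601, 0.218, 0.198 and 0.154). Its median was 1.08 without control M44448 and 1.25 without knockout M44440. Of 9 basal epithelial markers 8 were positive (median 0.40, adjusted p = 0.0260, and adjusted p = 0.563 with an estimated correlation), and the call was lost without M43768, M43767 or M44440 (median 0.16, 0.24 and 0.39, adjusted p = 0.579, 0.0724 and 0.0594). Knockout M43767 had the highest mean log2 value of this list (5.27 against 4.91 to 5.01 in the other knockouts), although its Acta2 was the lowest of the knockouts (105 FPKM). M43767 also held the skin keratin gene Krt10 at 53.5 FPKM, and whether skin in the tissue piece added to the basal markers was not tested. The 10 luminal markers had a median of -0.03 and a camera adjusted p of 0.736, and the mean of the list differed by 0.0048 ± 0.172 (exact permutation p = 1), with the sign of the median turned without M43768, M43767 or M44176 (0.11, 0.06 and 0.06). None of the cell type markers passed the threshold singly or adjusted over its list alone. In all, 9 of 27 lists passed at involution, 6 higher and 3 lower, and none with an estimated correlation, where 2 lists had an unadjusted p under 0.05 (STAT3 targets 0.00398, milk proteins 0.0306). Of the lists that passed, fry gave an unadjusted p under 0.05 for STAT3 targets (7.28e-04), cell cycle (0.0262) and milk proteins (1.93e-04, with the listed-at-0 gene Csn1s2a among the members). For the others the fry p ran from 0.0735 (NF-kB targets) to 0.363 (adipocytes). Without control M43768, 4 lists passed.

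The remaining lists at involution did not pass. Cytokines and receptors that use JAK1 split evenly (18 tested, median 0.01, adjusted p = 0.690). Adjusted over the list alone, Osmr, the oncostatin M receptor gene (28.2 ± 3.02 and 14.1 ± 3.39 FPKM), and Il4ra were lower, and Il11ra1 (18.8 ± 1.68 and 31.1 ± 5.58 FPKM) was higher. Interferon-stimulated genes also went both ways (53 tested, 30 positive, median 0.07, adjusted p = 0.894). Among them Rsad2, the antiviral viperin, was lower adjusted over the list alone (3.52 ± 0.350 and 1.69 ± 0.211 FPKM), while Ifi27l2a stood at 247 ± 137.9 and 1109 ± 544 FPKM (adjusted p = 0.417). Immediate early and stress genes had a median of 0.04 over 13 members (adjusted p = 0.402), with Fos, part of the AP-1 factor, lower adjusted over the list alone (25.3 ± 2.80 and 11.9 ± 3.97 FPKM). Median log2 differences were 0.11 for MHC class I presentation (adjusted p = 0.690), 0.02 for MHC class II presentation (0.840), -0.08 for STAT5 targets and lactation regulators (0.159) and 0.14 for milk lipid synthesis (0.572). They were -0.17 for lysosome and cathepsins (adjusted p = 0.261), -0.15 for cell death (0.135) and -0.07 for the TGF-beta pathway (0.611). Among cell types they were 0.15 for endothelium (adjusted p = 0.241), -0.22 for neutrophils (0.496), -0.03 for T and NK cells (0.402) and -0.31 for B and plasma cells (0.382). Skeletal muscle had 0.27 (adjusted p = 0.611) and erythrocytes -0.69 (0.217). Lymph node stroma and skin keratinocytes had 1 and 2 members past the expression filter and were not tested. For the receptors and the immediate early genes the mean and the test had the opposite sign to the median, and for luminal markers the mean did.

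At day 7 of lactation 1 gene passed the threshold, and markers of fat and vessels were higher as lists in the knockouts. In simulated data of this design 17.9% and 59.1% of genes well above the expression filter and changed by 1 and 2 on the log2 scale passed. Genes that did not pass are therefore not shown to be alike. All 11 adipocyte markers had a positive log2 difference in the knockouts (median 0.89, camera adjusted p = 2.44e-13, and adjusted p = 0.269 with an estimated correlation), and 4 were higher adjusted over the list alone. Among them Plin1, a coat protein of lipid droplets, stood at 3.10 ± 0.521 FPKM in the controls and 9.50 ± 2.28 FPKM in the knockouts (n = 3 each, adjusted p over all genes 0.644 with limma), and Car3, a carbonic anhydrase abundant in fat, at 141 ± 25.9 and 356 ± 68.1 FPKM (adjusted p = 0.998). All 7 endothelial markers were positive too (median 0.63, camera adjusted p = 5.51e-10, and adjusted p = 0.428 with an estimated correlation), with 4 higher adjusted over the list alone, such as Tie1, an endothelial receptor kinase, at 1.58 ± 0.123 and 3.20 ± 0.0746 FPKM. Such small p with the preset correlation do not exclude chance. In another split of the lactation libraries some list had a camera p of 1.33e-20, against 1.02e-14 for adipocytes in the real one.

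Of 9560 genes tested at lactation, 1 passed the threshold, Rn45s, a ribosomal RNA entry that was listed at 0 in the controls and at 508 to 3982 FPKM in the knockouts. Without knockout M44174, M42734 or M43767 it missed the expression filter and no gene passed, and with it left out as a gene listed at 0 in 1 whole group no gene passed. Under the main setting an unadjusted p under 0.05 was found for 228 genes (2.38%), and 579 genes (6.06%) did not overlap between the groups, where chance gives 10%. With array weights 9 genes passed, among them Hba-a2, Gsn, Tshb, Htra3 and Plin1. Without controls M42186 and M44175 the numbers were 2, gene a among them, and 3. None of the genes named next passed the threshold in the main setting. Hba-a2, an alpha globin gene, stood at 16.9 ± 10.97 FPKM in the controls and 0.481 ± 0.541 FPKM in the knockouts (log2 difference -3.45 ± 0.40, adjusted p = 0.127), and passed without control M44175 (adjusted p = 0.0415), with scaling to the total outside the milk proteins (0.0389) and with array weights (8.66e-04). Its near-identical copy Hba-a1 stood at 7.30 ± 5.87 and 28.8 ± 14.5 FPKM, so the division of reads between the copies is uncertain. Gsn, the actin-severing gelsolin, stood at 45.99 ± 9.42 and 113.1 ± 12.97 FPKM, and Htra3, a secreted protease, at 1.89 ± 0.254 and 5.66 ± 0.943 FPKM. Lower in the knockouts were Tshb, a subunit of thyrotropin (3.80 ± 1.51 and 0.919 ± 0.112 FPKM), Igf1, insulin-like growth factor 1 (8.97 ± 3.30 and 2.93 ± 1.58 FPKM), Sectm1a (12.6 ± 1.81 and 4.87 ± 2.70 FPKM) and Cyba, an NADPH oxidase subunit (13.3 ± 4.89 and 6.16 ± 0.320 FPKM). Gene a stood at 215, 321 and 186 FPKM in the knockouts and at 652, 1.54 and 1.33 FPKM in the controls.

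Of 24 lists tested at lactation, 5 passed, 4 higher and 1 lower, and none with an estimated correlation, where adipocytes and endothelium had an unadjusted p under 0.05 (0.0112 and 0.0356). Fibroblast markers were higher (8 tested, 7 positive, median 0.71, adjusted p = 1.54e-05, and adjusted p = 0.488 with an estimated correlation), with a median of 0.38 without control M43768 and of 1.24 with array weights. Pdgfra, a receptor of fibroblasts, stood at 0.578 ± 0.387 FPKM in the controls and 1.45 ± 0.0557 FPKM in the knockouts. Milk lipid synthesis genes were higher (30 tested, 20 positive, median 0.26, adjusted p = 0.0147, and adjusted p = 0.488 with an estimated correlation), led by Dgat2, an acyltransferase of triglyceride synthesis, at 12.4 ± 1.09 and 31.2 ± 13.3 FPKM. That call was lost with array weights (median 0.10, adjusted p = 0.198) and without control M44175 (median 0.08, adjusted p = 0.337) or knockout M44174 (median 0.22, adjusted p = 0.0514). Immediate early and stress genes were lower (8 tested, 7 negative, median -0.37, adjusted p = 0.00508, and adjusted p = 0.488 with an estimated correlation), such as Ier2 at 7.61 ± 1.32 and 4.68 ± 0.354 FPKM. That call was lost without knockout M44174 (median -0.27, adjusted p = 0.0643) and without control M42186, where the median was 0.11 (adjusted p = 0.828), and the median was -0.69 without control M44175 and -0.58 without knockout M42734. No member of the fibroblast, milk lipid or immediate early lists passed adjusted over the list alone. The list of STAT3 targets and acute phase genes had 14 of 27 members positive and a median of 0.02 (adjusted p = 0.978; -0.07 without M44175 and -0.02 without M44174), and interferon-stimulated genes had 22 of 33 negative and a median of -0.13 (adjusted p = 0.120). Interferon-stimulated genes passed with array weights (median -0.18, adjusted p = 0.0149) and without control M42186 or knockout M43767 (median -0.21 and -0.23, adjusted p = 5.90e-04 and 1.84e-04), among alternatives from 1.84e-04 to 0.995, and their median was 0.02 without M44174. The other 17 lists had adjusted p from 0.0715 to 0.978. The cell cycle list had a mean of the opposite sign to its median and test, and the erythrocyte list, in which Hba-a2 was lower adjusted over the list alone, had a median of the opposite sign to its mean and test. In exact permutation tests of the list means, adipocytes were higher by 0.91 ± 0.24 and endothelium by 0.61 ± 0.17 in the knockouts, each with p = 0.1, the smallest that 3 against 3 libraries allow (adjusted 0.6). Without control M42186, 8 lists passed.

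**Figure D2:**
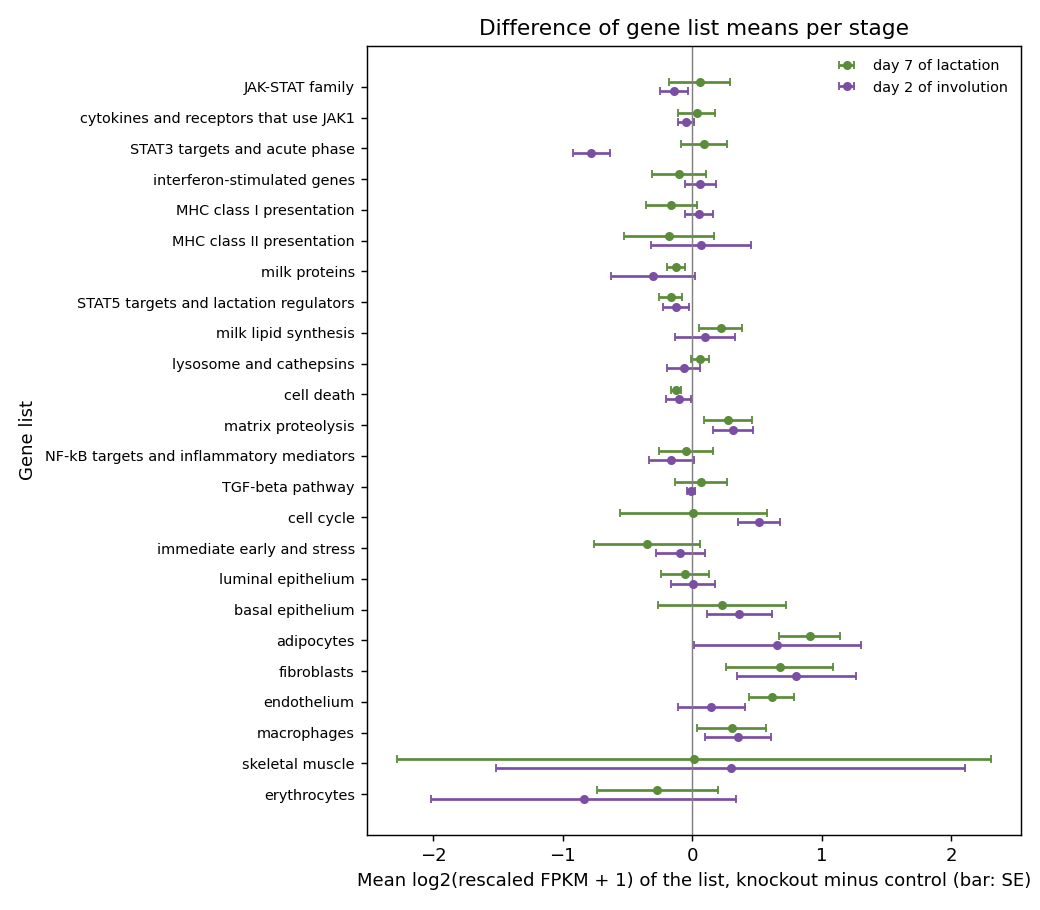
Difference, knockout minus control, of the mean log2(rescaled FPKM + 1) of each gene list at day 7 of lactation (green) and day 2 of involution (purple), with bars of 1 standard error, for lists tested at both stages and without genes listed at 0 in every library of 1 group. The STAT3 list lies at -0.78 at involution and 0.09 at lactation, and the adipocyte list at 0.91 at lactation.

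Among genes tested at both stages, the effect of the knockout differed for Spp1 and, at levels near the expression filter, for Tnnt2. Spp1 had a contrast, involution effect minus lactation effect, of -6.63 ± 0.82 on the log2 scale (adjusted p = 0.00547), with controls and knockouts at 548 ± 98.7 and 1449 ± 827 FPKM at lactation. Tnnt2, a troponin T, had a contrast of 1.63 ± 0.23 (adjusted p = 0.0189), with a log2 difference of -0.53 at lactation and 1.10 at involution, and Nfasc one of -1.32 ± 0.19 (adjusted p = 0.0190), which rests on involution because Nfasc was below the expression filter at lactation. Tnnt2 was low at both stages. It stood at 1.38 to 1.81 FPKM in the lactation controls and at 0.633 to 0.889 FPKM in the lactation knockouts. At involution it stood at 0.646 to 0.982 FPKM in the controls and at 1.91 to 3.32 FPKM in the knockouts. Of 12667 genes 10 passed, 2 with a positive and 8 with a negative contrast, and 424 (3.35%) had an unadjusted p under 0.05. The other 7 were the genes listed at 0 in 1 whole group, namely Csn1s2a, Trf, Cdk8, Rn45s and the microRNA entries Mir7036b, Mir1905 and Mir22, the last also chosen after its values were seen and listed at 0 in the lactation controls and at 14.3 to 87.6 FPKM in the knockouts. Without these genes Spp1 alone passed, and Tnnt2 and Nfasc had an adjusted p of 0.0633 each (0.0776 and 0.0820 with short RNA entries left out too). With scaling to the total outside the milk proteins both lost the threshold as well (adjusted p = 0.99983 and 0.0624), as Nfasc did with a pseudocount of 0.1 (0.99987). Spp1 passed in all 23 alternative settings (adjusted p up to 0.0391). Tnnt2 and Nfasc lost the threshold without M42186, M44175, M44174, M42734 or M43767 at lactation (adjusted p of Tnnt2 0.0761, 0.0506, 0.0988, 0.0938 and 0.0566, and of Nfasc 0.0806, 0.0817, 0.116, 0.0938 and 0.102). Tnnt2 also did without M43768 or M43914 at involution (adjusted p = 0.101 and 0.102), and Nfasc was not tested without any of the 3 involution controls. The number of genes was 6 without M42734 at lactation and 6 without M43768 or M43914 at involution. It was 16 with array weights and 20 with the mouse number as a block, 13 of them not listed at 0 in 1 whole group, such as S100a4 and Saa3.

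Among the lists, the STAT3 list differed between stages and did so with an estimated correlation too. Of its 31 members 24 had a negative contrast (median -0.46, camera adjusted p = 4.57e-06, and adjusted p = 0.0158 with an estimated correlation), 7 of them adjusted over the list alone. The list passed in all 24 alternatives, with a median from -0.75 to -0.36. At lactation, however, only 27 members passed the expression filter. Socs3 (0.155 to 0.795 FPKM over the lactation libraries) and Osmr (0.590 to 1.41 FPKM) lay near or below it. The contrasts of such members rest largely on involution, whereas others such as Lcn2 (307 to 1186 FPKM) were well above the filter at lactation. Of 27 lists 3 others passed with the preset correlation only. All 28 cell cycle members had a positive contrast (median 0.56, adjusted p = 3.53e-05, and adjusted p = 0.877 with an estimated correlation), but the median was 0.04 without lactation control M42186 (adjusted p = 0.685), 0.36 without M42734, 0.85 without M44174 and 0.87 without M44175 at lactation. Endothelial markers had a median of -0.40 (adjusted p = 0.0150, and adjusted p = 0.877 with an estimated correlation). The call was lost without M44175 or M43767 at lactation (median -0.30 and -0.31, adjusted p = 0.0568 and 0.101) and without M44448, M43196 or M44440 at involution (median -0.29, -0.29 and -0.31, adjusted p = 0.224, 0.0988 and 0.0655). Milk proteins had a median of -0.21 (adjusted p = 0.00211, and adjusted p = 0.317 with an estimated correlation). Without the listed-at-0 gene Csn1s2a the median was -0.19 (adjusted p = 0.389), and without lactation control M44175 it was 0.08. It was -0.34 and -0.38 without lactation controls M42186 and M43768, and -0.12 without involution knockout M44440. That call was also lost without M44448, M43768 or M43914 at involution (median -0.14, -0.03 and -0.22, adjusted p = 0.170, 0.659 and 0.807). Adipocytes, higher at lactation, had a median contrast of -0.35 that did not pass (adjusted p = 0.586). Without control M44448 at involution 2 lists passed, and 9 did with array weights and 8 with the mouse number as a block. For the cytokine receptor and NF-kB lists the mean and the test, for the STAT5 list the mean, and for the B and plasma cell list the mean and the test had the opposite sign to the median.

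Among the 9464 genes tested at both stages none passed at lactation, so an overlap of genes past the threshold could not be tested. Log2 fold changes of the stages correlated weakly across genes, which are not independent replicates (Pearson 0.139, Spearman 0.0205), and 48.2% had the same sign. Set side by side from separately made tables and not tested, control levels at lactation and involution were 3.82 ± 1.52 and 829 ± 149 FPKM for Igfbp5, an insulin-like growth factor binding protein of involution, and 644 ± 472 and 10085 ± 3172 FPKM for Lcn2, a lipocalin. Socs3 stood at 0.477 ± 0.320 and 23.4 ± 4.51 FPKM, Stat3 at 8.97 ± 2.80 and 97.0 ± 13.9 FPKM, and Jak1 at 11.5 ± 4.57 and 24.3 ± 0.332 FPKM. The milk protein gene Lalba, alpha-lactalbumin, stood at 14777 ± 9428 and 11462 ± 6796 FPKM, and Csn2 and Wap were listed at 0 in all libraries.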

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

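Of the tests in this part, the counts of splits for all calls, for lists and for genes listed at 0 were set before the results were seen. The tests of failed estimates, lost transcripts, luminal share, single libraries, scaling, shared reads, share of epithelium, splits of genes not listed at 0 at involution or in the difference between stages, and splits of the STAT3 list or of any list were chosen only after the result was seen.

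Values that stand apart in 1 library could be tested only among the 4 knockouts at involution. A gap to the nearest other library above 0.829 of the range was found in 14 of 151 items, where chance gives about 7.55. M43196, the library of lowest relative depth (0.513), held 6: Alas2 19.8, Hbb-bt 161.7, S100a8 216, Aurka 3.08, Cdc20 5.05 and Nfasc 0.468 FPKM. M44176 held 4: the muscle genes Ckmt2 (40.5) and Myh2 (14.9), Prlr (6.61) and Zfp36 (16.8). M43767 held 3: the keratin genes Krt10 (53.5) and Krt15 (73.9), and Acta2, which was low at 105 against 219, 228 and 225 FPKM. M44440 had a mean log2 value of the milk lipid list of 5.69 against 6.51 to 6.58. The source of these values, blood, muscle or skin in the tissue piece among others, was not tested.

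The effect of the knockout differed between stages, by the joint fit, for 10 genes and 4 lists. Tested at both stages were Spp1 (-6.63) and Tnnt2 (1.63), the latter at levels near the expression filter. Nfasc (-1.32) was below the expression filter at lactation, so its contrast rests on involution. Spp1 passed in all 23 alternatives, whereas Tnnt2 and Nfasc lost the threshold in some, with adjusted p up to 0.99983 and 0.99987. The fitted contrasts of genes listed at 0 in 1 whole group depend on the pseudocount and are no bounds: Csn1s2a -14.84, Mir7036b -9.40, Mir1905 -7.21, Trf 12.53, Rn45s -10.67, Cdk8 -3.67 and Mir22 -4.95. The lists were STAT3 targets and acute phase (median -0.46), milk proteins (-0.21), cell cycle (0.56) and endothelium (-0.40). With an estimated correlation the STAT3 list passed (adjusted p = 0.0158) and the other 3 did not (0.317, 0.877 and 0.877). Of 100 random splits of the libraries within both stages, 1, the real one, gave as many as 10 genes (highest other 4), of which 7 are listed at 0 in 1 whole group. As many as 3 genes not listed at 0, short RNA entries left out, also came from 1 of the 100, the real one (highest other 2). In a fit without the genes listed at 0, however, Spp1 alone passed. The splits were not repeated without those genes, so chance is not excluded for the genes not listed at 0. As many as 4 lists came from 83 of the 100 splits (highest other 16), so chance is not excluded for the number of lists. These splits were not scored for the STAT3 list alone, so they do not test it.

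The first pattern is the lower STAT3 and acute phase list in the knockouts at involution. Of 35 splits of the 7 libraries 1, the real one, gave this list as small a camera p (1.08e-11, smallest other 6.18e-10), but some list had as small a p in 9 of 35 splits (smallest other 2.89e-21) and as many as 9 lists came from 15 of 35 (highest other 13), so chance is not excluded for a list picked among 27. Its adjusted p was 0.108 with an estimated correlation. The adjusted p of 0.386 by exact permutation cannot decide on chance, since it could pass only if many lists reached the smallest p. The tables argue against a smaller luminal share as the whole cause, since the list fell relative to the luminal list (-0.7843 ± 0.177, exact permutation p = 0.0286, the smallest possible). The 10 luminal markers went both ways (4 higher, 6 lower), so their mean is only a rough measure of that share. The tables also argue against 1 library, since every leave-out kept a median of -0.5107 or lower. They argue against the scaling of libraries within the table, since 3 other scalings kept -0.626 or lower. Reads shared between the Saa and Orm copies are argued against as the whole cause, since without these 5 genes the median of the other 26 was -0.4029 (camera p = 3.02e-06, and p = 0.00849 with an estimated correlation). What stays open is a change in cells other than luminal epithelium. Fibroblast (median 0.77), adipocyte (0.69), basal epithelial (0.40) and macrophage markers (0.35) were higher with the preset correlation only (adjusted p = 0.563, 0.780, 0.563 and 0.657 with an estimated one). The macrophage call was lost without M43196 (adjusted p = 0.161), as the adipocyte and basal calls were without some libraries. Neutrophil markers were not past the threshold (-0.22). A difference in the time of involution between mice and the authors' processing before the table stay open too and were not tested. Relative depth overlapped between the groups (0.735 to 1.24 in controls, 0.513 to 1.59 in knockouts). The effect of JAK1 on STAT3 output itself was not tested, and Hp, Il1r1, Nupr1 and Itih4 stood the other way.

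The second pattern is genes listed at 0 in all libraries of 1 group. At involution 5 genes were, and as many came from 3 of 35 splits (highest other 6), so chance is not excluded for them. The values fit estimates that failed in the authors' processing, since 6 milk protein genes were listed at 0 in all lactation libraries, where such transcripts abound. A loss of the transcript in the group at 0 cannot be told apart from this. Of the 5, 3 (Csn1s2a, Mir7036b and Mir1905) were also at 0 in all lactation libraries of both groups, so for them a 0 says nothing of the genotype. The casein Csn1s2a is among the milk protein genes at 0 there. Cdk8 and Trf stood above 0 in all lactation libraries, so for them both explanations stay open. As many as 9 genes came from 1 of 35 splits, the real one (highest other 6). No other split reached that sum, but 1 of 35 is the smallest share possible, and the sum holds the 5 listed at 0. For the 4 genes not listed at 0 chance is not excluded, since as many came from 2 of 35 splits. The other split was M43768, M43914, M43196 and M44440 against M44448, M43767 and M44176.

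The third pattern is the higher adipocyte list in the knockouts at lactation, where 3 against 3 libraries give 10 splits, too few to test chance. For genes the number was 1 (highest other 3, with as many in 8 splits), and for lists 5 (highest other 9, with as many in 7). In another split some list had a camera p of 1.33e-20, below the 1.02e-14 of the adipocyte list in the real split. The tables argue against control M44175, which stood apart, as the cause, since its mean log2 value of the list (4.91) lay nearer the knockouts than those of controls M42186 and M43768 (4.46 and 4.51). Leaving M44175 out was therefore bound to widen the difference and is no separate test (median 1.226, adjusted p = 1.56e-16 with the preset correlation). With all libraries the list does not pass with an estimated correlation (adjusted p = 0.269). A lower share of epithelium in the knockout samples stays open, since the adipocyte list rose relative to the macrophage list by 0.6019 ± 0.389 (exact permutation p = 0.3). The mean log2 values of the luminal and basal lists differed by -0.057 ± 0.186 and 0.228 ± 0.495, with errors that leave room for a lower share. A different fat content of the tissue piece and an effect of JAK1 on the gland's fat stay open too and were not tested.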

How the results depend on the processing

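The fits without genes listed at 0 in every library of 1 group, those also without short RNA entries, and all alternatives for the lists of the difference between stages other than that with a replicate block were chosen only after the results were seen. Values below are numbers of genes or lists past the threshold, log2 differences of genes, or median log2 differences of lists.

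At lactation the main setting gave 1 gene and 5 lists. The number of genes was 2 with scaling to the total outside the milk proteins, 2 with a pseudocount of 0.1, 9 with array weights, and 0 without genes listed at 0 in 1 whole group, also when short RNA entries were left out too. The number of lists was 8 with no filter, 10 with array weights and 0 with an estimated inter-gene correlation. Leaving out 1 library gave 0 (without M44174, M42734 or M43767) to 3 genes (without control M44175) and 5 to 8 lists (8 without control M42186).

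At involution the main setting gave 9 genes and 9 lists. The number of genes was 20 with scaling to the total outside the milk proteins, 14 with robust empirical Bayes, 20 with array weights, 1 without genes listed at 0 in 1 whole group, and 3 when short RNA entries were left out too. No list, 0 of 27, passed with an estimated inter-gene correlation. Leaving out 1 library gave 2 (without control M44448 or M43768) to 9 genes (without knockout M44440) and 4 (without control M43768) to 12 lists (without knockout M43196). In a fit that leaves out a library the groups hold at least 2.

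For the difference between stages the main setting gave 10 genes and 4 lists. The numbers were 16 genes and 9 lists with array weights, and 20 genes and 8 lists with the replicate block, that is, with the number in the title as a block (consensus correlation 0.6971). Without genes listed at 0 in 1 whole group 1 gene passed, as when short RNA entries were left out too, and 1 list passed with an estimated inter-gene correlation. Leaving out 1 library gave 6 (without M42734 at lactation, or without M43768 or M43914 at involution) to 12 genes (without knockout M43767 at involution) and 2 (without control M44448) to 5 lists. The block takes libraries with the same number as 1 mouse. Deviations from the group means of such libraries correlated at 0.0918 (M43768) and 0.274 (M43767) over 9464 genes, within the range of other pairs (-0.471 to 0.506), so the tables do not settle whether they share a mouse.

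Directions turned in results that were past no threshold in the main setting, apart from immediate early genes at lactation and milk proteins in the difference. Scaling to the total outside the milk proteins moved the median of all genes by 0.219 at lactation and by -0.190 in the difference. With it the lactation values of Jak1 (0.25), Jak2 (0.14), Stat5a (0.22), Elf5 (0.13), Epcam (0.13), Krt18 (0.13), the interferon list (0.075) and the luminal list (0.16) turned, of which Jak1 and Stat5a lay above that shift. With array weights Jak3 (-0.12), Stat3 (-0.28), Stat6 (-0.10), Cldn4 (0.20), the STAT3 list (-0.012) and the luminal list (0.048) turned at lactation. With FPKM as deposited Stat3 (-0.021) and the STAT3 list (-0.029) did, and with a pseudocount of 0.1 Jak1 did (0.0073).

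Leaving out 1 library at lactation gave ranges of -0.41 to 0.22 for Jak1, -0.17 to 0.030 for Jak2, -0.19 to 0.33 for Jak3, -0.094 to 0.34 for Stat2, -0.23 to 0.25 for Stat3, -0.28 to 0.15 for Stat5a, -0.10 to 0.20 for Stat6, -0.0055 to 0.44 for Tyk2 and -1.08 to 0.15 for Fos. For lists the ranges were -0.69 to 0.11 (immediate early), -0.066 to 0.16 (STAT3), -0.23 to 0.020 (interferon) and -0.17 to 0.033 (luminal). At involution they were -0.18 to 0.11 for Stat6, -0.032 to 0.23 for Tyk2 and -0.13 to 0.11 for the luminal list, and in the difference -0.38 to 0.078 for milk proteins.

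Of the values of named genes other than Jak1 and of lists, under the alternatives that keep all libraries, 15 turned direction, 38 lost the threshold and 16 gained it, while under those that leave out 1 library 23 turned, 57 lost and 4 gained it. Where a call or direction changed without a cause given here, the cause was not tested. Nfasc and genes listed at 0 in 1 whole group could not be tested where leaving out 1 library left fewer than 3 libraries at 1 FPKM.

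At these group sizes a simulated change of 1 on the log2 scale, in genes well above the expression filter, was found for 17.9% at lactation and 32.8% at involution. The effect of depth was not tested, since the simulations did not vary it.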

Other observations

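No test of this part was chosen after the results were seen, since leaving out 1 library was planned and no other was made. Markers of tissue beside the gland's epithelium varied between libraries. Acta1, a skeletal muscle actin, stood at 1525 FPKM in M44176 and 417 FPKM in M44448 at involution and at 293 FPKM in M44174 at lactation. Krt10, a skin keratin, stood at 53.5 FPKM in M43767 at involution, and Cd79a, a B cell gene, at 14.3 FPKM in M43768 at lactation. Gene a stood at 652 FPKM in lactation control M42186, at 0.521 to 1.54 FPKM in the other 5 controls and at 186 to 439 FPKM in the 7 knockouts. Whether its level follows the knockout, the coat colour background of the mice, neighbouring sequence or a wrong label of M42186 was not tested, and a wrong label would bear on every lactation comparison. Without M42186, 2 genes and 8 lists passed at lactation, where 1 gene and 5 lists did with it.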
